A study of Pelodiscus sinensis with 18 samples.

How the data were processed

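RNA was measured in liver and gut of the Chinese soft-shelled turtle, Pelodiscus sinensis, after exposure to niclosamide, a drug against worms that is also used to kill snails. The labels give 3 libraries for each of 6 groups, which are unexposed controls, 10 µg per L (nic10) and 50 µg per L (nic50) in each tissue. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. CASAVA is the only tool named, per the submitters' processing notes. The aligner, the counting tool and the genome build are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be only technical.

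The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of a library), with 24880 features in 18 libraries, per the file headers. FPKM values are scaled by transcript length and by sequencing depth, and no read counts were used here. Depth could not be worked out from the smallest values. The commonest ratio between low values of a pair of libraries was shared by 0.618% to 1.52% of low genes, too few to mark the value of 1 read. The depth behind each value is therefore unknown, and no counting interval is given. FPKM sums ran from 588542 to 699273 in liver and from 677583 to 753840 in gut. An exact 0 in such a table can be a failed estimate. Of 176 housekeeping genes with a median FPKM of at least 10 in liver, 1 was at 0 in some library, and 0 of 175 were in gut. The deposited table was used as it stands.

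Gene symbols were taken from the table for 13431 features. A further 975 features with only a number were named through the RefSeq annotation of assembly ASM4963464v1, which was used for names and chromosomes and not for coordinates, because the build behind the table is not given. A symbol found this way is printed with its identifier. Reads shared between near-identical copies could have been split by the counting, so paralogs are uncertain.

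Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with the spread moderated along mean expression. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Genes with FPKM of at least 1 in at least 3 libraries of a fit were tested. Each tissue was fitted on its own with its 3 dose groups, which share 1 estimate of the spread. Differences between tissues came from 1 fit of all 18 libraries, in which the interaction at a dose is the liver change minus the gut change. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. Gene lists were tested with limma's camera, with a correlation between genes preset to 0.01, and again with that correlation estimated from the data. No list call held with an estimated correlation. There were 30 pathway lists and 23 lists of cell type markers, and a list with at least 5 tested members was tested.

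The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, among genes with a symbol past the threshold whose 3 exposed libraries lie on 1 side of all 3 controls, the 10 with the highest and the 10 with the lowest log2 fold change. It adds, for each list that passed camera, up to 4 members with the smallest p in the direction of the list, and SOD1, SOD2, CAT, GPX1, GSR, NFE2L2, KEAP1, HMOX1 and NQO1 in every exposure comparison. For fewer than 5 genes past the threshold it names the 5 with the smallest p in each direction whether past or not. For the nic50 against nic10 comparisons and the interactions it names up to 5 past the threshold in each direction. Between tissues it names ALB, APOB, FGB, TTR, VIL1, CDX2, FABP2 and MYH11, of which ALB and TTR matched no symbol in the table. The report prints the members that bear on each list and not every gene the rule names. Genes named outside the rule are stated to have been chosen after their values were seen.

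The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling by trimmed means, quantile normalization, library weights, a fold change of at least 2, a replicate block, fits of only the groups compared, and leaving out each library. A fit with alike livers averaged, a covariate for a set of genes present in 5 libraries, and a fit without gut nic10 libraries 1 and 3 were chosen after seeing the data. In the fit with averaged livers the nic50 group had a single value, which was assumed to vary like the others.

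The fit was tested on simulated data drawn around the measured means and spreads. Only genes with a high mean were changed there, so recovery of low genes, such as SST in liver and FGG in gut, was not measured. All groups were given the same spread and genes were drawn independently, while the real groups differ in spread. In each comparison 100 genes were changed at each size, while 22 genes passed in the real gut nic10 comparison and 3 in gut nic50. The adjusted threshold is stricter when fewer genes pass, so recovery there could be lower than in the simulation. Genes changed by 1 on the log2 scale were recovered at 59% in both liver comparisons with control, 62% in gut nic10 and 54% in gut nic50. For a change of 2, recovery was 91% in liver nic10, 94% in liver nic50, 93% in gut nic10 and 91% in gut nic50. Interaction changes of 1 were recovered at 27% for nic10 and 28% for nic50, and changes of 2 at 76% and 83%. The liver comparisons ran on 10892 genes, the gut comparisons on 12617 and the interactions on 13475. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.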

Results

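Liver and gut transcriptomes of soft-shelled turtles were compared between unexposed animals and animals exposed to niclosamide at 10 µg per L (nic10) or 50 µg per L (nic50). The series title sets these data beside antioxidant defence and tissue structure. Each of the 6 groups held 3 libraries. Liver libraries had 9440 to 10839 features at an FPKM of at least 1, and gut libraries 11534 to 12340. The 10 most abundant features took 21.4% to 29.5% of the FPKM sum in liver and 13.4% to 21.9% in gut. Sequencing depth is unknown for these values.

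The tissue labels were borne out by marker genes in the controls. FGB, a fibrinogen chain made by hepatocytes, was higher in liver by a log2 value of 11.88 (SE 0.39, limma adjusted p = 2.22e-13), with 19396 ± 2277 FPKM against 4.14 ± 0.57 (SD, n = 3). APOB, the lipoprotein scaffold, was higher in liver by 2.98 (SE 0.42). CDX2, an intestinal transcription factor, averaged 51.2 ± 5.36 FPKM in gut (SD, n = 3), a log2 value of -5.70 in liver relative to gut. FABP2 (-6.09) and VIL1 (LOC102459110, -6.66), which mark absorptive enterocytes, and the smooth muscle gene MYH11 (-3.88) were also lower in liver. In all, 8634 of 13475 genes differed, 1700 higher in liver and 6934 lower. The median log2 difference over all tested genes was -0.58, and the split became 3476 higher and 3345 lower after rescaling by trimmed means and 3064 higher and 3697 lower after quantile normalization.

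Libraries within a group were not alike in spread. The 3 nic50 livers correlated at 0.990 to 0.993 across genes, while nic10 livers correlated at 0.929 to 0.968 and control livers at 0.957 to 0.991, the highest being controls 2 and 3. Genes are not independent replicates in these correlations. A set of 12 genes was present in liver controls 2 and 3, gut controls 1 and 2 and gut nic50 library 3, and near 0 in the other 13 libraries. Of its members 3 lie on chromosome 15 of the reference assembly, and the others have no known place in it. Mitochondrial transcripts took 16.9% to 23.1% of the FPKM sum in control livers, 9.61% to 10.998% in nic50 livers, and 8.18%, 19.4% and 11.3% in nic10 livers 1, 2 and 3.

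**Figure D1:**
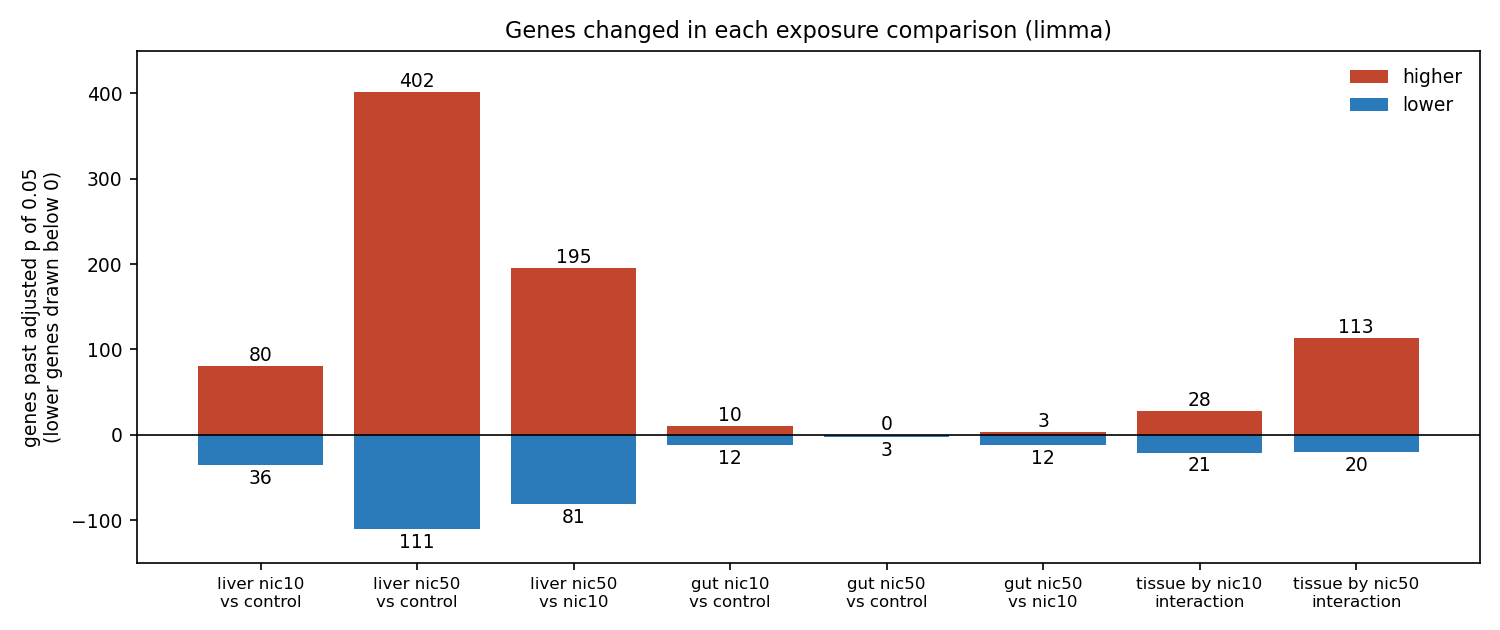
Number of genes past a Benjamini-Hochberg adjusted p of 0.05 (limma) in each exposure comparison, with higher genes drawn above 0 and lower genes below it. Liver nic50 against control has the tallest bar, with 402 higher and 111 lower genes, and gut nic50 has 0 higher and 3 lower.

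At the lower dose, 116 of 10892 genes differed between exposed and control livers, 80 higher and 36 lower. SST, which encodes the hormone somatostatin, rose from 0.502 ± 0.437 to 9.62 ± 1.85 FPKM (SD, n = 3; log2 fold change 2.86, SE 0.26, adjusted p = 0.00107), with 1 control library listed at 0. ENTPD3, an ectonucleotidase, fell from 8.86 ± 1.85 to 0.841 ± 0.413 FPKM (log2 fold change -2.43, SE 0.22, adjusted p = 0.00107). EPO, the erythropoietin gene, rose by 1.72 (SE 0.27, adjusted p = 0.0195) and NR0B2, a nuclear receptor that represses bile acid synthesis, changed by -2.06 (SE 0.36, adjusted p = 0.0263). SST and ENTPD3 passed in all 6 fits without 1 library, and EPO and NR0B2 in 3.

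SFTPD, a collectin that binds microbes, reached 144 ± 122 FPKM against 9.66 ± 6.22 (SD, n = 3; log2 fold change 3.61, SE 0.65, adjusted p = 0.0313). TNFRSF6B, a decoy receptor for death ligands, reached 344 ± 363 FPKM against 20.1 ± 3.95 (3.37, SE 0.66, adjusted p = 0.0417). MARCO, a scavenger receptor of macrophages, rose by 1.68 (SE 0.26), and the flagellin receptor TLR5 by 1.28 (adjusted p = 0.0332). Of 6 fits without 1 library SFTPD and TNFRSF6B passed in 2 and TLR5 in 3, and MARCO passed in 1 of the 3 that tested it. None of the 4 passed with alike livers averaged, where the residual degrees of freedom fell from 6 to 3 and the fold changes were 3.93, 3.40, 1.73 and 1.32 in the order named. COLXVI (2.40), OLFML3 (2.25), RARRES1 (2.001), TMEM109 (1.95) and TSTD3 (1.77) were the other genes named for a rise. Among the lower genes were ADIPOR2 (-1.82), a receptor for adiponectin, ELOVL5 (-1.34), which elongates polyunsaturated fatty acids, PCOLCE (-1.77), which assists procollagen processing, HES4 (-1.62), MAP3K6 (-1.003), TULP2 (LOC102448162, -2.02), GUCA2A (LOC102460033, -1.96) and HSD3B1 (LOC102453952, -1.51), a steroid-forming dehydrogenase.

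Of 39 lists tested in nic10 livers, 8 passed camera with a preset correlation, and each had an adjusted p = 0.945 with an estimated correlation. In the list for the unfolded protein response, 2 of 32 members rose, ERO1A (1.40, adjusted p = 0.0224) and CRELD2 (1.504, adjusted p = 0.0338), and 5 rose adjusted over the list alone. ERO1A and CRELD2 each passed in 3 of 6 fits without 1 library. The median log2 fold change of this list was 0.50 (camera adjusted p = 7.45e-08), and SEC61A1 (0.99, adjusted p = 0.0957) and PDIA6 (1.01, adjusted p = 0.101) did not pass. Its mean was 0.47, 0.21 and 0.96 in nic10 libraries 1, 2 and 3, highest in library 3, against -0.12, 0.07 and 0.06 in controls. Of 27 inflammatory genes TLR5 alone rose over all genes tested and 2 adjusted over the list alone (median 0.47, camera adjusted p = 0.00088), while SOCS3 had a log2 fold change of 2.42 (adjusted p = 0.161). The mean of that list was 0.10, 0.55 and 0.76 in nic10 libraries 1, 2 and 3 and at most 0.11 in controls, so library 1 lay within the controls. The 11 markers of stellate cells and fibroblasts had a median of 0.37 (camera adjusted p = 0.0446), with 0 past the test and 2 higher adjusted over the list alone; DCN stood at 1.03 (adjusted p = 0.0823) and COL3A1 (LOC102447978) at 0.98 (adjusted p = 0.0773).

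Lists of energy metabolism passed in the lower direction in the same livers, again with adjusted p = 0.945 with an estimated correlation. Of 72 nuclear genes of the respiratory chain 1 fell, NDUFA1 (-0.89, adjusted p = 0.0437), also the only one adjusted over the list alone, and the list median was -0.21 (camera adjusted p = 1.19e-06). NDUFA1 passed in 2 of 6 fits without 1 library, and the list mean stood at 0.16 relative to control in nic10 library 1, above every control, against -0.51 and -0.42 in libraries 2 and 3. Of 13 genes of the mitochondrial genome 0 passed over all genes (median -0.57, camera adjusted p = 0.00635), and adjusted over the list alone 2 fell and 1 rose. ND1 had a log2 fold change of -1.63 (adjusted p = 0.125) and COX1 of -1.66 (adjusted p = 0.145), with nic10 library 2 at 11345 FPKM for COX1 against 2405 and 3392 in the others; the list mean was -1.18, 0.14 and -0.62 in libraries 1, 2 and 3. The lists of the citric acid cycle (34 genes, median -0.12, camera adjusted p = 0.0423) and fatty acid oxidation (40 genes, median -0.09, camera adjusted p = 0.0259) had 0 members past the test, and adjusted over the list alone 1 and 0 fell. The former list stood at -0.02, -0.23 and -0.17 in nic10 libraries 1, 2 and 3 against -0.20, 0.08 and 0.12 in controls, and the latter at -0.12, -0.17 and -0.40 against -0.15, 0.04 and 0.11, so 2 libraries and 1 lay within the controls. Values were -0.82 for PC (adjusted p = 0.0532), -1.20 for CD36 (adjusted p = 0.127) and -1.02 for CPT1A (adjusted p = 0.182). Of 73 ribosomal protein genes RPS28 fell (-0.98, adjusted p = 0.0493), also the only one adjusted over the list alone, with a list median of -0.13 (camera adjusted p = 0.00538). RPS28 passed in 2 of 6 fits without 1 library, the ribosomal list stood at 0.40, -0.24 and -0.55 in nic10 libraries 1, 2 and 3, and its median was 0.078 without nic10 library 3.

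The count in nic10 livers fell from 116 to 7 when the alike livers were averaged, and was 569, 17 and 25 without controls 1, 2 and 3, and 501 and 63 without nic10 libraries 1 and 3. SST, COLXVI and ENTPD3 passed in each of these fits, of the 25 named genes past the test 7 passed in all 6 fits without 1 library, 16 of 97 placed genes lie on chromosome 15 and all 16 were higher, and the 80 higher and 36 lower became 59 and 44 after rescaling by trimmed means and 63 and 62 after quantile normalization. The balance turned without control 1, with 266 higher and 303 lower, and with library weights, with 773 higher and 910 lower. With a covariate for the 12-gene set, which sets exposed livers against control 1 alone, 29 genes passed and 12 of the 116 were among them.

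At the higher dose, 513 of 10892 genes differed between exposed and control livers, 402 higher and 111 lower, with a median log2 fold change of 0.13 over all tested genes. CISH, an inhibitor of cytokine signalling, rose from 1.66 ± 0.701 to 13.4 ± 0.361 FPKM (SD, n = 3; log2 fold change 2.47, SE 0.23, adjusted p = 0.000498). DIO2, which activates thyroid hormone, rose from 1.68 ± 0.601 to 14.6 ± 4.44 FPKM (2.53, SE 0.25, adjusted p = 0.000747). SCD, the desaturase that makes monounsaturated fatty acids, stood at 591 ± 57.3 FPKM against 142 ± 81 (2.19, SE 0.42, adjusted p = 0.0179). LGALS3, a galectin of macrophages and epithelia, fell from 86.1 ± 20.9 to 18.2 ± 2.18 FPKM (-2.16, SE 0.22, adjusted p = 0.000747).

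Other genes with a rise in nic50 livers were BST1 (3.30, SE 0.64), MGP (2.94, SE 0.51), an inhibitor of calcification, the collagen-modifying PLOD2 (LOC102445695, 2.61, SE 0.26), APOLD1 (2.28), UCHL1 (2.09), TMEM119 (2.02), which lies on chromosome 15, and KLF10 (2.01). HPGDS, a prostaglandin D synthase, fell from 13.8 ± 4.99 to 0.482 ± 0.155 FPKM (SD, n = 3; -3.26, SE 0.38, adjusted p = 0.00119). DHRS1, a dehydrogenase, stood at 0.493, 0 and 0.382 FPKM in nic50 livers against 34.4, 158 and 155 in controls (-6.23, SE 1.34, adjusted p = 0.0281), and at 137, 16.4 and 0 in nic10 livers. GNLY (LOC102447230, -5.14), LGALS4 (-2.52), RET (-2.37), PRR35 (-1.95) and CENPV (-1.92) fell as well.

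**Figure D2:**
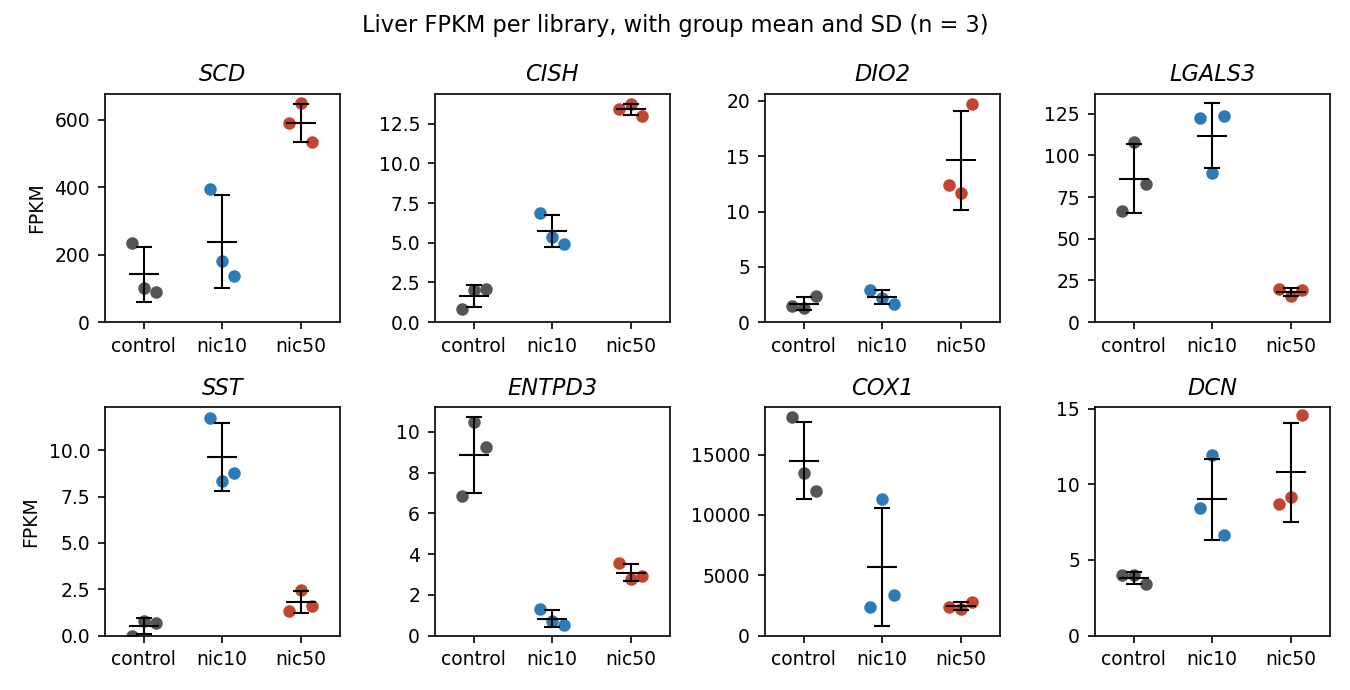
FPKM of 8 genes in each liver library by dose group (points), with the group mean and SD (n = 3, bars). SCD, CISH and DIO2 were highest in nic50 livers and LGALS3 and COX1 lowest, SST was highest and ENTPD3 lowest in nic10 livers, and DCN averaged 10.8 FPKM in nic50 livers against 3.81 in controls.

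Lists of matrix genes and of matrix-forming cells passed in the higher direction in nic50 livers. Of 27 extracellular matrix genes 7 rose, and 13 adjusted over the list alone, with a median of 0.67 (camera adjusted p = 3.78e-05; adjusted p = 0.979 with an estimated correlation). COL14A1 rose by 1.11 (SE 0.15, adjusted p = 0.00319), COL6A3 by 1.45 (SE 0.22, adjusted p = 0.00609), the fibrillar collagen COL3A1 (LOC102447978) by 1.40 (SE 0.23, adjusted p = 0.00745) and the proteoglycan DCN by 1.26 (SE 0.24, adjusted p = 0.0186). Of 11 markers of stellate cells and fibroblasts 5 rose, and 9 adjusted over the list alone, with a median of 1.02 (camera adjusted p = 2.88e-05; adjusted p = 0.979 with an estimated correlation). These included HAND2 (1.47, adjusted p = 0.0276) and COL1A1 (1.06, adjusted p = 0.0404), and COL3A1, DCN and COL1A1 belong to both lists. COL3A1 passed in 5 of 6 fits without 1 library, COL6A3 in 4, DCN in 1, HAND2 and COL1A1 in 0, and COL14A1 in the 3 that tested it. The marker list averaged 0.74, 0.77 and 1.28 above the control mean in nic50 livers 1, 2 and 3.

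Of 13 genes of the mitochondrial genome 3 fell and 1 rose in nic50 livers. COX1 fell by 2.55 on the log2 scale (SE 0.48, adjusted p = 0.0165), ND1 had a log2 fold change of -2.17 (SE 0.45, adjusted p = 0.0241) and COX2 of -1.53 (adjusted p = 0.0381), while ATP8, named after its value was seen, rose by 1.58. Of 6 fits without 1 library COX1 passed in 2, and ND1 and COX2 in 0. The list of 13 had a median of -0.59 (camera adjusted p = 2.13e-05; adjusted p = 0.979 with an estimated correlation), and adjusted over the list alone 4 fell and 1 rose. Of 72 nuclear genes of the respiratory chain 0 passed, also adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.00803; adjusted p = 0.979 with an estimated correlation). List means were 0.08, -0.06 and -0.17 in nic50 libraries 1, 2 and 3 against 0.11, 0.04 and -0.15 in controls, so libraries 1 and 2 lay within the controls. Of 21 cholesterol synthesis genes EBP (0.99, adjusted p = 0.0147) and MVK (1.01, adjusted p = 0.0284), which lies on chromosome 15, rose, each passing in 1 of 6 fits without 1 library, and 6 rose adjusted over the list alone. Their median was 0.46 (camera adjusted p = 0.0263; adjusted p = 0.979 with an estimated correlation), with INSIG1 at 1.05 (adjusted p = 0.0508) and FDPS at 0.75 (adjusted p = 0.054).

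The count in nic50 livers fell from 513 to 4 when the alike livers were averaged, and was 188, 163, 113, 87 and 63 without control 2, control 3 and nic50 libraries 1, 2 and 3. CISH, DIO2, LGALS3, HPGDS, PLOD2 (LOC102445695), UCHL1, TMEM119, KLF10, RET, PRR35 and CENPV passed in all 6 fits without 1 library, SCD, BST1, DHRS1 and GNLY in 1, APOLD1 in 0, and of the 42 named genes past the test 0 passed with alike livers averaged. There the residual degrees of freedom fell from 6 to 3, while the fold changes were 2.60 for CISH, 2.58 for DIO2, -3.39 for HPGDS and -2.08 for LGALS3, against 2.47, 2.53, -3.26 and -2.16 with all libraries. Among the placed genes 50 of 429 lie on chromosome 15, all 50 higher, against 2.40% of the genes tested, and the 402 higher and 111 lower became 226 and 169 after rescaling by trimmed means and 286 and 221 after quantile normalization. With the covariate for the 12-gene set, again against control 1 alone, 1104 genes passed and 290 of the 513 were among them.

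**Figure D3:**
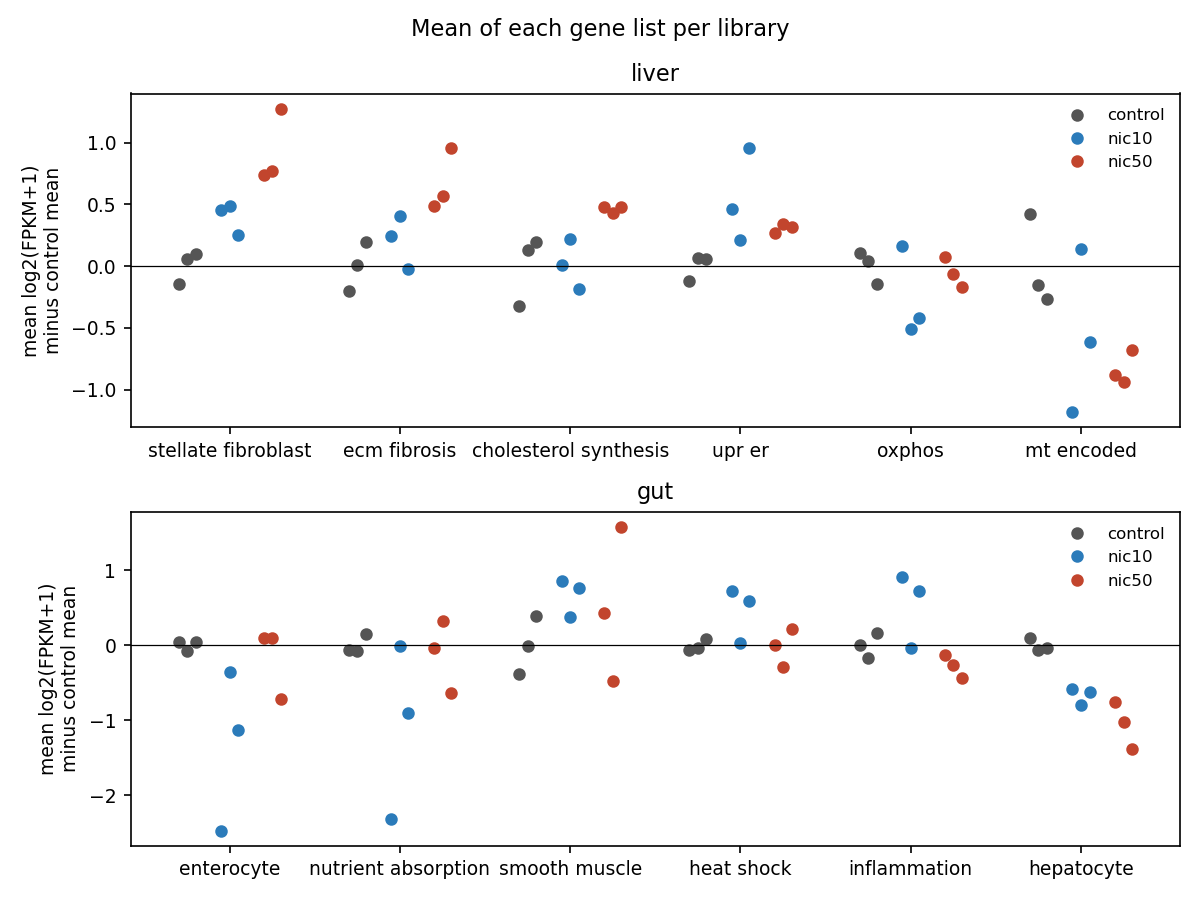
Mean log2(FPKM + 1) of each gene list in each library minus the mean of the control libraries of that tissue, with 1 point per library. The stellate cell and fibroblast list lies between 0.74 and 1.28 in nic50 livers, and the enterocyte list at -2.47, -0.35 and -1.13 in nic10 guts.

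The doses were set against each other in liver, where 276 genes differed, 195 higher and 81 lower at nic50 than at nic10. HSD3B1 (LOC102453952) stood at 17.5 ± 1.9 FPKM at nic50 against 1.06 ± 0.704 at nic10 (SD, n = 3; log2 difference 3.21, SE 0.25, adjusted p = 0.000172). THNSL2 (1.97), the opioid precursor PDYN (1.82), SPOCK3 (1.49) and PLOD2 (LOC102445695, 2.44) were also higher at nic50. LGALS3 (-2.55, SE 0.22, adjusted p = 0.000257), UNC93A (-2.05), COLXVI (-2.13), the helicase gene RTEL1 (-1.96) and the lysosomal peptidase gene DPP7 (-1.67) were lower. Of the genes that differed from control, 31 were higher and 14 lower at both doses, and HSD3B1 alone changed in opposite directions. Of the 31 shared higher genes 8 lie on chromosome 15, whose genes could differ with the 12-gene set of control livers 2 and 3 rather than with the dose. Independent lists of these sizes would share 2.95 and 0.367 genes, a figure that ignores the shared controls. Simulated groups with no effect, with controls drawn anew, shared 0. That count cannot test the overlap, since with no effect hardly any gene passes. The fold changes at the doses correlated at 0.445 across genes, against 0.497 in 100 such simulations, and their covariance was 0.1004 against 0.0447. Part of the overlap may come from the shared controls, which are too few to split. The count of 276 fell to 4 with alike livers averaged and was 1434, 167 and 140 without nic10 libraries 1, 2 and 3 and 37, 42 and 42 without nic50 libraries 1, 2 and 3. With alike livers averaged HSD3B1 stood at 3.21 and LGALS3 at -2.54, neither past the test.

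In gut at the lower dose, 22 of 12617 genes differed from control, 10 higher and 12 lower, with a median log2 fold change of 0.11 over all tested genes. LEAP2, an antimicrobial peptide and ghrelin receptor antagonist, fell from 134 ± 49.4 to 7.61 ± 3.85 FPKM (SD, n = 3; log2 fold change -4.01, SE 0.46, adjusted p = 0.0131). The fibrinogen genes FGG (-2.18, SE 0.16, adjusted p = 0.00111) and FGA (-1.71, SE 0.17, adjusted p = 0.00548) fell, from 4.99 ± 0.351 to 0.322 ± 0.134 FPKM and from 3.22 ± 0.391 to 0.292 ± 0.107 (SD, n = 3). Liver RNA in the control gut libraries could also give this fall, and is weighed below. PAXX, a DNA repair factor, changed by -1.64 (SE 0.18, adjusted p = 0.0102), and HGFAC, the activator of hepatocyte growth factor, rose by 2.32 (SE 0.34, adjusted p = 0.0454).

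Genes of absorptive enterocytes stood lower in nic10 guts, but no single member passed over all genes. The peptide transporter gene SLC15A1 averaged 1.6 ± 2.76 FPKM against 410 ± 386 (SD, n = 3; -6.99, adjusted p = 0.148), and the brush border peptidase genes ACE and MEP1A had log2 fold changes of -4.44 (adjusted p = 0.121) and -3.34 (adjusted p = 0.251). VIL1 (LOC102459110) stood at -1.18 (adjusted p = 0.164). The 18 enterocyte markers had a median of -0.87 (camera adjusted p = 9.44e-08) with 2 lower adjusted over the list alone, and the 37 nutrient absorption genes a median of -0.80 (camera adjusted p = 1.86e-08) with 3 lower. Both had adjusted p = 0.755 with an estimated correlation. The enterocyte list stood at -2.47, -0.35 and -1.13 relative to the control mean in nic10 libraries 1, 2 and 3, and the absorption list at -2.31, -0.01 and -0.91.

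Another 12 of the 42 lists tested passed in nic10 guts. Of 15 acute phase and complement genes FGG, FGA and LEAP2 fell, and 5 adjusted over the list alone (median -0.24, camera adjusted p = 8.43e-05; adjusted p = 0.319 with an estimated correlation). Of 8 hepatocyte markers FGG and FGA fell, and 3 adjusted over the list alone (median -0.94, camera adjusted p = 1.69e-05; adjusted p = 0.107 with an estimated correlation). Liver RNA in control guts could give part of the fall in both lists. The other 10 lists had 0 members past the test over all genes and 0 adjusted over the list alone, except 1 higher endothelial gene. Those in the lower direction were nuclear respiratory chain genes (median -0.14, camera adjusted p = 1.72e-08), amino acid breakdown (median -0.17, camera adjusted p = 0.0264), lipid synthesis and lipoproteins (median -0.13, camera adjusted p = 0.0114) and T and NK cell markers (median -0.38, camera adjusted p = 0.000586), each with adjusted p = 0.755 with an estimated correlation. Mitochondrial genome genes (median -0.31, camera adjusted p = 0.04) and cell cycle genes (median -0.12, camera adjusted p = 0.0114) passed in the same direction, with adjusted p = 0.834 with an estimated correlation. The cell cycle list stood at -0.05, -0.09 and -0.15 in nic10 libraries 1, 2 and 3, all within the controls (-0.04, -0.27 and 0.31), and the respiratory chain list at -0.02, -0.36 and -0.05, where only library 2 lay below the lowest control (-0.10). Also within the controls were library 3 for T and NK cell markers (-0.15) and library 2 for smooth muscle markers (0.37). In the higher direction were heat shock proteins (median 0.29, camera adjusted p = 0.0114), extracellular matrix (median 0.41, camera adjusted p = 0.0132) and smooth muscle markers (median 0.70, camera adjusted p = 0.0426), with adjusted p = 0.834 with an estimated correlation. Endothelial markers had a median of 0.52 (camera adjusted p = 0.00299; adjusted p = 0.755 with an estimated correlation). Examples were HSPB8 (1.91, adjusted p = 0.251), FBLN1 (2.13, adjusted p = 0.214), VWF (0.87, adjusted p = 0.197) and MYH11 (0.93, adjusted p = 0.342). Heat shock genes averaged 0.72, 0.03 and 0.59 above control in nic10 libraries 1, 2 and 3, the same libraries 1 and 3 that had the lowest enterocyte values. Means of the mitochondrial genome (-0.72, 0.50 and -0.76), lipid (-0.77, 0.05 and -0.27) and amino acid (-0.17, -0.22 and 0.16) lists did not share a sign over these libraries.

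The count in nic10 guts was 4, 5 and 43 without controls 1, 2 and 3, 6, 190 and 7 without nic10 libraries 1, 2 and 3, and 1 without nic10 libraries 1 and 3. LEAP2 passed in 3 of 6 fits without 1 library, PAXX in 2 and HGFAC in 1. FGG and FGA passed without each nic10 library, and were not tested without a control, since only the 3 controls reached an FPKM of 1. Without nic10 libraries 1 and 3 together, which leaves a group of 1 library, they stood at -2.19 and -1.84, values that rest on that library.

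In gut at the higher dose, 3 of 12617 genes differed from control with limma, all lower, and 820 had an unadjusted p under 0.05. FGG fell to 0.343 ± 0.0651 FPKM (SD, n = 3; log2 fold change -2.16, SE 0.16, adjusted p = 0.00372) and FGA to 0.195 ± 0.035 FPKM (-1.82, SE 0.17, adjusted p = 0.00649). The other was LOC102450868, named after its values were seen, with 1.27 to 3.37 FPKM in nic50 guts and 41.5 to 70.1 in controls. EGR1 and FOS, immediate early transcription factors, had log2 fold changes of -1.87 (adjusted p = 0.198) and -1.68 (adjusted p = 0.306), and CD200R1 (-1.17) and the hepatocyte protease gene HPN (-1.67) an adjusted p = 0.198. In the higher direction the smallest p-values were those of TRIM45 (1.20, adjusted p = 0.198), LENG1 (1.09, adjusted p = 0.306), and NAT9 (1.19), ISYNA1 (0.84) and TBATA (1.34), each with adjusted p = 0.386.

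Of 42 lists in nic50 guts 17 passed camera with a preset correlation. FGG and FGA fell among 15 acute phase and complement genes (median -0.84, camera adjusted p = 3.1e-08; adjusted p = 0.0707 with an estimated correlation), where 5 fell and 1 rose adjusted over the list alone. They also fell among 8 hepatocyte markers (median -0.72, camera adjusted p = 2.67e-06; adjusted p = 0.0656 with an estimated correlation), where 3 fell adjusted over the list alone. Liver RNA in control guts could give the fall of FGG and FGA, and part of that of both lists. FGB, the other fibrinogen chain, had a log2 fold change of -1.9999 (adjusted p = 0.532). The other 15 lists had 0 members past the test over all genes. Immune and vascular lists stood lower, namely inflammation (median -0.29, camera adjusted p = 0.00399, 1 lower adjusted over the list alone; adjusted p = 0.714 with an estimated correlation), macrophages (median -0.69, camera adjusted p = 0.00192, 1 lower adjusted over the list alone), interferon response (median -0.24, camera adjusted p = 0.00192), antigen presentation (median -0.26, camera adjusted p = 0.016) and endothelium (median -0.46, camera adjusted p = 7.04e-05). The last 4 had adjusted p = 0.521 with an estimated correlation. The macrophage list stood at -0.65, -0.04 and -0.74 in nic50 libraries 1, 2 and 3 and the inflammation list at -0.13, -0.26 and -0.43, so library 2 for the former and library 1 for the latter lay within the controls (lowest -0.21 and -0.17). PTGS2, the inducible cyclooxygenase, stood at -1.16 (adjusted p = 0.234) and LYVE1 at -1.13 (adjusted p = 0.572).

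Lower lists in nic50 guts also included immediate early and clock genes (median -0.15, camera adjusted p = 0.00436; adjusted p = 0.521 with an estimated correlation), with 2 lower adjusted over the list alone. Enteroendocrine markers (median -0.48, camera adjusted p = 0.000761; adjusted p = 0.129 with an estimated correlation) included CCK at -2.06 (adjusted p = 0.637) and SST at -1.18 (adjusted p = 0.66). Tight junction and mucus genes (median -0.20, camera adjusted p = 0.00224; adjusted p = 0.707 with an estimated correlation), the integrated stress response (median -0.14, camera adjusted p = 0.0353) and the unfolded protein response (median -0.13, camera adjusted p = 0.0441) had 0 members lower adjusted over the list alone, the last pair with adjusted p = 0.783 with an estimated correlation. Higher lists, each with 0 members adjusted over the list alone, were ribosomal proteins (median 0.12, camera adjusted p = 3.48e-06) and smooth muscle (median 0.44, camera adjusted p = 0.000646), with adjusted p = 0.783 with an estimated correlation. Cholesterol synthesis (median 0.31, camera adjusted p = 0.00192; adjusted p = 0.521 with an estimated correlation), fatty acid oxidation (median 0.08, camera adjusted p = 0.0235; adjusted p = 0.559 with an estimated correlation) and mitochondrial genome genes (median 0.30, camera adjusted p = 0.0396; adjusted p = 0.868 with an estimated correlation) passed in that direction too. Relative to control in nic50 libraries 1, 2 and 3, the smooth muscle list stood at 0.43, -0.48 and 1.58, the mitochondrial genome list at -0.52, 0.42 and 0.88, with library 1 below every control, fatty acid oxidation at 0.22, 0.29 and -0.03, cholesterol synthesis at 0.21, 0.59 and 0.03, with library 3 within the controls, tight junction and mucus genes at 0.04, -0.44 and -0.34, and the unfolded protein response at 0.0077, -0.16 and -0.23. The count of 3 became 0 and 14 without controls 1 and 3, where FGG and FGA were not tested for want of 3 libraries at an FPKM of 1, and 7 and 5 without nic50 libraries 1 and 2.

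Between the doses in gut 15 genes differed, 3 higher and 12 lower at nic50, with a median log2 difference of -0.13 over all tested genes. The complement gene C8G was higher at nic50 (2.06, SE 0.27, adjusted p = 0.0302), and PLVAP (-1.90, SE 0.24, adjusted p = 0.027) and a copy of it, PLVAP (LOC102446149, -1.90, SE 0.26, adjusted p = 0.042), which form the diaphragms of capillary pores, were lower. Each of the 3 passed in 2 of 6 fits without 1 library. FGG, FGA and LOC102450868 were lower than control at both doses. Independent lists would share 0.00285 genes, which ignores the shared controls. Simulated groups with no effect shared 0.01, which cannot test the overlap, since hardly any gene passes there. The gut fold changes correlated at 0.448 across genes against 0.501 in 100 simulations, with a covariance of 0.0903 against 0.0608, and part of the overlap may come from the shared controls. The count of 15 was 2, 367 and 2 without nic10 libraries 1, 2 and 3, 4 and 3 without nic50 libraries 1 and 2, and 3 without nic10 libraries 1 and 3.

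The antioxidant genes that the naming rule adds in every exposure comparison did not pass the test in either tissue at either dose. In nic10 livers GPX1 had a log2 fold change of 0.71 (SE 0.21, adjusted p = 0.161), SOD1 of -0.68 (SE 0.30, adjusted p = 0.35) and HMOX1 of -0.75 (SE 0.28, adjusted p = 0.263). CAT (0.35), GSR (0.15), KEAP1 (LOC102454403, 0.27), NFE2L2 (-0.01), NQO1 (-0.04) and SOD2 (-0.12) had adjusted p-values of 0.545 to 0.993. In nic50 livers GPX1 stood at 0.55 (adjusted p = 0.172) and SOD2 at 0.56 (adjusted p = 0.199). CAT (0.38), GSR (0.51), HMOX1 (0.33), KEAP1 (0.50), NFE2L2 (0.04), NQO1 (-0.09) and SOD1 (-0.06) had adjusted p-values of 0.252 to 0.932, and NFE2L2 changed sign after either rescaling. Of the 42 genes of the whole antioxidant list 4 rose in nic50 livers, also adjusted over the list alone, namely the thioredoxin reductase genes TXNRD1 (0.99) and TXNRD2 (1.07), GLRX2 (0.89) and GPX8 (0.84), named after their values were seen. TXNRD2 passed in 4 of 6 fits without 1 library, GLRX2 in 1 and TXNRD1 in 0, GPX8 in 0 of the 3 that tested it, and none of the 4 passed with alike livers averaged, where they stood at 1.01 (TXNRD2), 0.89 (GLRX2), 1.09 (TXNRD1) and 0.81 (GPX8) on fewer degrees of freedom. That list did not pass camera there (adjusted p = 0.612, and 0.979 with an estimated correlation), nor in nic10 livers (0.694), nic10 guts (0.256) or nic50 guts (0.931). In nic10 guts NQO1 stood at -0.61 (adjusted p = 0.315), and CAT (-0.12), GPX1 (0.18), GSR (0.34), HMOX1 (-0.37), KEAP1 (0.30), NFE2L2 (0.14), SOD1 (-0.22) and SOD2 (-0.01) had adjusted p-values of 0.486 to 0.987, with SOD2 changing sign after quantile normalization. In nic50 guts CAT (-0.17), GPX1 (-0.14), GSR (0.13), HMOX1 (-0.53), KEAP1 (0.42), NFE2L2 (-0.15), NQO1 (0.03), SOD1 (0.02) and SOD2 (0.13) had adjusted p-values of 0.846 to 0.995.

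Whether the tissues differed in their change was tested directly. At nic10 the change differed between liver and gut for 49 of 13475 genes, 28 with a higher value in liver and 21 lower. SST had a log2 difference of 4.40 (SE 0.50, adjusted p = 0.000323), rising in liver while guts stood at 38.9, 19.9 and 25.3 FPKM in controls and 8.48, 6.50 and 11.4 at nic10. FGG (2.57, SE 0.23, adjusted p = 5.7e-05) and FGA (2.06, SE 0.22, adjusted p = 0.000198) fell in gut and did not pass the test in liver, where control means were 23524 ± 1150.4 and 14275 ± 1080.2 FPKM (SD, n = 3). Their fall in gut could come from liver RNA in the control gut libraries. At nic50 the change differed for 133 genes, 113 higher and 20 lower. DIO2 (2.63, SE 0.29, adjusted p = 0.000416), PTGS2 (2.48, SE 0.33, adjusted p = 0.00161) and FGG (2.23, SE 0.23, adjusted p = 0.000204) moved upward in liver relative to gut, and HPGDS (-2.55, SE 0.46, adjusted p = 0.0131), LGALS3 (-2.26, SE 0.37, adjusted p = 0.0078) and RET (-2.26, SE 0.36, adjusted p = 0.00653) downward. The count of 49 was 200, 16 and 21 without liver controls 1, 2 and 3, 103 and 27 without liver nic10 libraries 1 and 3, 22 without gut control 1, and 20, 175 and 14 without gut nic10 libraries 1, 2 and 3; the count of 133 was 79 without liver control 3, 74, 66 and 36 without liver nic50 libraries 1, 2 and 3, and 70 and 80 without gut controls 1 and 2. With alike livers averaged the counts fell to 13 and 5, and the nic50 split of 113 and 20 became 81 and 32 after rescaling by trimmed means and 68 and 29 after quantile normalization.

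**Figure D4:**
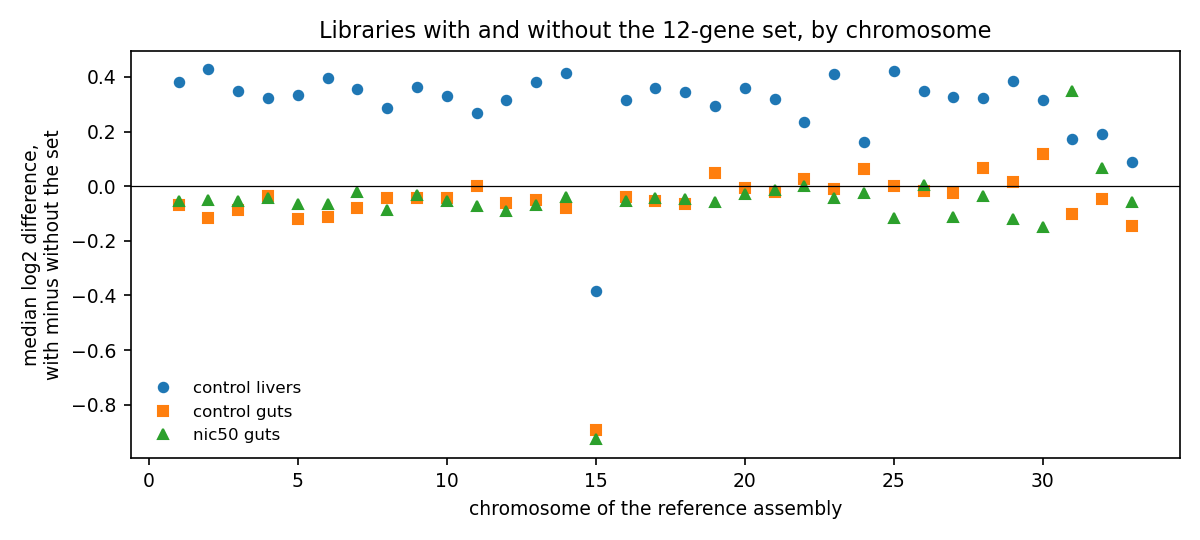
Median log2 difference between libraries with and without the 12-gene set, for the genes of each chromosome of assembly ASM4963464v1, in control livers, control guts and nic50 guts. Chromosome 15 has the lowest median in each of the 3 groups, at -0.38, -0.89 and -0.93.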

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

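Tests of the alike livers for a shared source and for depth, of the 12-gene set for failed estimates, and of shared turtles were chosen after the result was seen. The other tests here had their predictions set before their result was seen, but of the bounds for liver RNA in gut the first was run second.

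The change with dose was compared between liver and gut by a test of the difference itself. It was not adjusted for the 12-gene set, which was spread unevenly over the groups. At nic10 this test passed for 49 genes. The difference in log2 fold change, liver minus gut, was 2.57 for FGG (SE 0.23, adjusted p = 5.7e-05), 2.06 for FGA (SE 0.22), 4.40 for SST (SE 0.50), 3.78 for LEAP2 (SE 0.53) and 1.39 for the complement gene C9 (SE 0.24, adjusted p = 0.0206). It was -2.01 for ENTPD3 (SE 0.31), -2.33 for HGFAC (SE 0.38), -1.54 for RHOBTB3 (SE 0.26), -2.23 for PCOLCE (SE 0.38) and -2.27 for HSD3B1 (SE 0.41, adjusted p = 0.0228). FGG, FGA, SST, LEAP2, ENTPD3 and HGFAC passed in each of the 12 fits without 1 library, and FGG, FGA, SST and LEAP2 with the alike livers averaged. Of 100 splits made within each tissue 5 gave as many genes, the highest other with 403, so chance is not excluded for the count of 49. The split with 403 kept the real groups and exchanged the gut labels, so it measured the sum of the changes in liver and gut. The count was 200, 16 and 21 without liver controls 1, 2 and 3, 103 and 27 without liver nic10 libraries 1 and 3, 22 without gut control 1, and 20, 175 and 14 without gut nic10 libraries 1, 2 and 3.

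At nic50 the test of the difference passed for 133 genes. The values were 2.23 for FGG (SE 0.23, adjusted p = 0.000204), 2.63 for DIO2 (SE 0.29), 1.79 for PDYN (SE 0.20), whose control livers were listed at 0, 1.84 for FGA (SE 0.22) and 2.48 for PTGS2 (SE 0.33). They were -2.004 for PRR35 (SE 0.27), -2.26 for RET (SE 0.36), -2.26 for LGALS3 (SE 0.37), -2.14 for HGFAC (SE 0.38) and -2.55 for HPGDS (SE 0.46, adjusted p = 0.0131). FGG, DIO2, PTGS2, FGA, PRR35, RET, LGALS3 and HGFAC passed in each of the 12 fits without 1 library, and FGG, DIO2, PDYN and PTGS2 with the alike livers averaged. Of 100 splits 4 gave as many genes, a share under 0.05, and the highest other gave 530. That split kept the real liver groups and set gut libraries with the 12-gene set against those without it, which points to a structure of the samples. The other 2, with 138 and 245 genes, also kept the real liver groups, and the latter exchanged the gut labels. Among the splits drawn, those that kept the real liver groups with other gut labels gave 33 to 530 genes. Those that broke up the liver groups gave at most 50. The share under 0.05 therefore rests on the liver groups, and cannot tell a difference between tissues from the liver change alone. The count was 79 without liver control 3, 74, 66 and 36 without liver nic50 libraries 1, 2 and 3, and 70 and 80 without gut controls 1 and 2.

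The 3 nic50 livers were more alike than other livers. Genes present in 1 library (FPKM of at least 5) and absent from another (at most 0.1) numbered at most 3 in a nic50 pair, against at least 13 in a pair from different groups, as a shared source, repeat libraries of 1 animal or 1 pool, would give. Greater depth is argued against, since the scatter of nic50 pairs at an FPKM of at least 100, where counting noise is small, was 0.273 of that of nic10 pairs. For a uniform response of separate animals, the ratio was 0.372 in 217 genes with no sign of a response. This cannot decide, because these genes were chosen by a high p in the same fits, which favours a wide spread in the other livers. In these genes control liver 2 differed from nic50 livers 1 and 3 by 0.124, against 0.0943 to 0.118 within nic50 pairs. Those were the lowest values of pairs from different groups, whose median was 0.193. Control liver 2 differed from nic50 liver 2 by 0.161. A uniform response remains open, and close relatives remain open and untested. Control livers 2 and 3 shared the likeness, with 6 genes present in 1 and absent from the other. If these libraries share a source, the liver p-values may rest on fewer animals than libraries.

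A set of 12 genes was present in 5 libraries and absent from 13. Failed estimates of single genes are argued against, since 12 genes shared the pattern and the next pattern had 1. Sex-linked gene copies that mark female turtles are a candidate explanation: genes of chromosome 15 had a median log2 difference of -0.74 between libraries with and without the set, while the lowest other chromosome stood at 0.000561. The set differed in 3 of 9 pairs of liver and gut with the same dose and number, which argues against liver and gut with the same dose and number coming from the same turtle. No exposed liver held the set, while control livers 2 and 3 did. Any gene that changed in exposed livers could therefore follow this difference rather than the dose. The chromosome 15 genes higher there (50 of 429 placed genes at nic50) are the clearest case. No nic10 gut held the set either, while control guts 1 and 2 did. In that comparison chromosome 15 genes had a median log2 fold change of 0.66, against 0.11 for other placed genes.

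FGA and FGG were lower in exposed guts than in control guts. Liver RNA in the control gut libraries is a candidate explanation, tested on other genes abundant in liver. The bound set first, run second, asked for a median log2 ratio of control to nic50 of 1.5 over 24 genes, and the value of 1.22 left the explanation undecided. A looser bound, set second and run first, asked for 1 at both doses, and the lower median was 1.34, but its 23 genes are nearly the same, FGB and LOC102461675 among them had been seen, and it is no independent test. FGA, FGB and FGG in control guts stood at 0.0205%, 0.0181% and 0.0188% of their liver level. In the same order they stood at 0.00124%, 0.00125% and 0.00129% in nic50 guts, and at 0.00186%, 0.00728% and 0.00121% in nic10 guts. Of the 23 genes 21 were higher in control than in nic10 guts, and 20 were higher in control than in nic50 guts. Both liver RNA and a lower expression in exposed guts remain open.

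Splits of 6 libraries number 10, too few for a share under 0.05. Counting the real split, as many genes were given by 2 splits in liver nic10 (116, highest other 191), 1 in liver nic50 (513, highest other 0), 1 in liver nic50 against nic10 (276, highest other 0), 1 in gut nic10 (22, highest other 8), 4 in gut nic50 (3, highest other 82), 2 in gut nic50 against nic10 (15, highest other 17) and 1 between tissues (8634, highest other 1). The gut split with 82 genes set the libraries with the 12-gene set against the others, and 57 of its genes lie on chromosome 15, which points to that structure of the samples.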

How the results depend on the processing

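The fit with alike livers averaged, the covariate for the 12-gene set and the fit without gut nic10 libraries 1 and 3 were chosen after the result was seen, and the other alternatives before. Except where stated, the cause was not tested.

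Liver nic10 (116 genes) gave 52 genes with no filter on low values, 1683 with array weights, 76 with the replicate block, 20 with only the 2 groups compared, 7 with alike livers averaged, 29 with the covariate (12 of the 116) and 17 to 569 without 1 library. Liver nic50 (513) gave 298 at a mean FPKM of at least 5, 4094 with array weights, 313 at a fold change of at least 2, 1137 with only the 2 groups compared, 4 with alike livers averaged, 1104 with the covariate (290 of the 513) and 63 to 718 without 1 library. Liver nic50 against nic10 (276) gave 137 at a mean FPKM of at least 5, 2267 with array weights, 4 with alike livers averaged, 699 with the covariate (all 276 among them) and 37 to 1434 without 1 library. In the comparisons with control, the covariate sets exposed livers against control 1 alone, the only control without the 12-gene set. Between the doses, where no liver held the set, it changed only the estimate of the spread. The median log2 difference there stayed at 0.101. Averaging leaves fewer libraries, and the mean FPKM and fold change settings leave fewer genes by construction.

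Gut nic10 (22 genes) gave 13 with pseudocount 0.1, 8 at a mean FPKM of at least 5, 746 with array weights, 5 with the covariate, 1 without nic10 libraries 1 and 3 and 4 to 190 without 1 library. Gut nic50 (3) gave 1 at a mean FPKM of at least 5, where FGG and FGA were not tested, 11 with only the 2 groups compared and 0 to 14 without 1 library. Gut nic50 against nic10 (15) gave 9 with pseudocount 0.1, 4 at a mean FPKM of at least 5, 478 with array weights, 3 with only the 2 groups compared, 3 with the covariate, 3 without nic10 libraries 1 and 3 and 2 to 367 without 1 library. FGA (-1.66) did not pass in gut nic10 with the covariate. A fit without nic10 libraries 1 and 3 assumes that the lone nic10 library varies like the other groups. There FGG stood at -2.19 and FGA at -1.84, values that rest on 1 nic10 library and show no stability.

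The tissue by nic10 interaction (49) gave 28 with pseudocount 0.1, 23 at a mean FPKM of at least 5, 1417 with array weights, 77 with the replicate block, 13 with alike livers averaged and 14 to 200 without 1 library. The tissue by nic50 interaction (133) gave 70 at a mean FPKM of at least 5, 575 with array weights, 5 with alike livers averaged and 36 to 158 without 1 library. Liver against gut in controls (8634) gave 4988 at a mean FPKM of at least 5, 4946 at a fold change of at least 2 and 7682 to 8339 without 1 library. Replicate numbers were not taken as pairs, because the labels do not say that they mark a shared tank, day or animal. Same-number libraries, compared afterwards, correlated at -0.19 to 0.25 in liver, -0.29 to 0.25 in gut and -0.22 to 0.26 across tissues, which does not settle the point.

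Some antioxidant genes, none of them past the test, and some list medians changed sign. In liver nic10 GSR was -0.032, NQO1 0.39 and the mitochondrial genome list (mt_encoded) -0.016 with array weights, the last because the test's direction and not the sign of the median turned. NFE2L2 was 0.062 with alike livers averaged, and KEAP1 was -0.077 and NFE2L2 0.28 with the covariate. In liver nic50 NFE2L2 was -0.13 with TMM rescaling, -0.095 with quantile normalization and -0.083 with array weights, where NQO1 was 0.15. In gut nic10 SOD2 was 0.0076 with quantile normalization, and GSR was -0.090 and KEAP1 -0.057 with the covariate. Without nic10 libraries 1 and 3 CAT was 0.71, HMOX1 0.012, SOD2 0.088, and the lists mt_encoded 0.63, heat_shock -0.030 and nutrient_absorption 0.19. In gut nic50 NQO1 was -0.039 with array weights, and GSR was -0.082 and SOD2 -0.073 with the covariate.

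Without 1 library, values in liver nic10 ran from -0.21 to 0.20 for NQO1, -0.15 to 0.093 for NFE2L2, -0.11 to 0.43 for GSR, -0.32 to 0.11 for SOD2 and -0.42 to 0.078 for the ribosome list. In liver nic50 they ran from -0.10 to 0.14 for NFE2L2, -0.25 to 0.11 for NQO1 and -0.11 to 0.0087 for SOD1. In gut nic10 they ran from -0.54 to 0.13 for CAT, -0.072 to 0.40 for GPX1 and -0.16 to 0.18 for SOD2. In gut nic50 they ran from -0.34 to 0.0077 for CAT, -0.14 to 0.40 for GSR, -0.16 to 0.27 for NQO1, -0.027 to 0.34 for SOD2, -0.39 to 0.083 for GPX1 and -0.050 to 0.15 for SOD1.

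TMM rescaling moved the median of all genes from 0.13 to -0.01 in liver nic50, from 0.11 to -0.01 in gut nic10, from -0.13 to 0.01 in gut nic50 against nic10 and from -0.58 to 0.00 between tissues. Of named genes past the test, 7 of 25 in liver nic10, 11 of 42 in liver nic50 and 8 of 10 in liver nic50 against nic10 passed in each of the 6 fits without 1 library. With alike livers averaged these were 3, 0 and 0, on 3 residual degrees of freedom instead of 6, with similar fold changes in some (CISH 2.60, LGALS3 -2.08). In gut 0 of 5 at nic10, 0 of 3 at nic50 and 0 of 3 between the doses passed in all 6, and FGG and FGA passed in the 3 fits that tested them. Depth is unknown, so what it limits could not be tested.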

Other observations

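These features were singled out after their values were seen, and no explanation was tested. LOC102443578 ranged from 409 to 1382 FPKM in control and nic10 livers and from 0 to 0.157 in nic50 livers. LOC112545245 ranged from 17.7 to 18.8 FPKM in nic50 livers and was listed at 0 in the other livers. In gut it stood at 15.9 in nic10 library 3, 70.9 in nic50 library 1 and 58.1 in nic50 library 3, and was listed at 0 in the others.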
